A study of Danio rerio with 69 samples.

How the data were processed

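Gene expression was measured in zebrafish (Danio rerio) pineal gland and in brain from which the pineal and the eyes had been removed. Per the labels, fish were kept at 28.5 °C under 14 h of light and 10 h of dark. Tissue was taken by day and by night at 3, 5 and 10 days (called larval here), at 3 months and at 1 to 2 years (adult). Pineal glands were dissected by hand, guided by green fluorescent protein under the promoter of aanat2. Total RNA was extracted with a lipid tissue kit, amplified and labelled with biotin, and each sample was hybridized to its own 1-colour Affymetrix Zebrafish Genome Array. There were 69 arrays in 20 groups of 2 to 5 biological replicates, 38 from pineal and 31 from brain.

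The deposited table held 1 linear intensity per probe set and array, for 15617 probe sets. The mean intensity of a column without its highest and lowest 2% of values lay between 500.1 and 500.2, so the deposited intensity values had been scaled to a common target on each array. The algorithm that combined the probes of a set is not given in the sources used here, and neither is any background correction. Median intensity per array ranged from 114.3 to 221.9. The number of arrays limits the precision of every comparison.

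A constant of 16 was added to each intensity before the log2 transform. Array medians then ranged from 7.03 to 7.89, a range of 0.87 that passed the limit of 0.5 fixed beforehand, so the log2 values were quantile normalized. The 115 control probe sets were left out, and 15502 were tested. Probe sets were named from the platform annotation, with symbols updated through gene identifiers. Of those tested, 10795 had 1 symbol, 135 had several and 4572 were unnamed here. For gene lists and named genes, each of 8793 genes was represented by its probe set of highest mean over all arrays.

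Comparisons used limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 20 groups, contrasts of these means were tested with moderated statistics (trend on mean level, 49 residual and 14.3 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg within each contrast. Tests of contrasts and of gene lists were two-sided. The hypergeometric tests of overlap and the permutation tests asked only for values as high or higher. Ages and sampling times had equal weight in contrasts averaged over them. Comparisons of tissues or stages required an adjusted p below 0.05 and a fold of at least 2; comparisons of night with day required an adjusted p below 0.05 alone. A limma F-test asked whether the night-day difference in pineal varied over the 5 ages. The p-values reflect the spread between the labelled biological replicates. Errors are standard errors from the limma fit unless named otherwise.

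Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over 22 lists within a contrast, with camera at an estimated correlation and fry beside it. The lists, written before the data were examined, were melatonin synthesis; phototransduction; photoreceptor structure and retinoid handling; photoreceptor and pineal transcription factors; circadian clock; light-responsive and DNA repair; heme synthesis and oxidative stress; oxidative phosphorylation and glycolysis; and cell cycle. Lists of marker genes for other cell types were retinal opsins and lens crystallins, neurons, habenula, astroglia and radial glia, oligodendrocytes and myelin, erythrocytes, immune cells, endothelium and blood vessels, skin and keratins, muscle, connective tissue with cartilage and bone, pigment cells, and pituitary and hypothalamic hormones. Named genes were chosen by a rule that was also written beforehand. For the tissue, night-day, stage and tissue-by-time comparisons, it took the 10 largest rises and 10 largest falls among called genes that had the same direction at every age. For the stage comparison both adult ages had to lie on the same side of the larval ages, and for tissue by time only the call was required. It also took from each list the called members of smallest adjusted p, or those of highest mean level where none was called. Counts adjusted over a list alone used the adjusted p without any fold limit. Clone-type names were counted but not quoted.

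The same steps were tested on simulated data with the array layout and spread of the study. Of 100 probe sets given a log2 change of 1.5, the tissue comparison recovered 100% and the night-day comparison in pineal 98%. At a change of 0.75, which lies below the 2-fold limit, the tissue comparison recovered 7%, and the night-day comparison recovered 48%. False calls numbered 0 and 3, and the one shifted list of 22 was called with 0 others. Each probe set was simulated independently of the others. The list result therefore does not extend to lists whose genes vary together between arrays.

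The alternatives tried were no scaling or median centring in place of quantile normalization, added constants of 1 and 64, a filter that kept the 10603 probe sets whose highest group mean passed the median of all values, no intensity trend, robust variances, array weights, only the arrays compared, other thresholds, a replicate block, and each age and each array left out in turn. After the data had been seen, 3 more were added. They were the 3'/5' signal ratio of the GAPDH control probe sets (a measure of RNA integrity) as a covariate, the fit without the 11 arrays where this ratio passed 3, and the count called at all 5 ages. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 in Python 3.11.15.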

Results

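Gene expression was compared on 69 arrays, 38 from zebrafish pineal gland and 31 from brain without pineal and eyes. The pineal is a light-sensitive gland at the roof of the brain that secretes melatonin at night. At 3 days there were 3 pineal arrays by day and 4 by night, and likewise 3 and 4 brain arrays. At 5 days there were 5 and 4 pineal arrays and 3 and 2 brain arrays, and at 10 days 4 and 4 pineal and 3 and 4 brain arrays. At 3 months every group held 3 arrays, and at 1 to 2 years there were 4 pineal arrays and 3 brain arrays at each sampling time. Median intensity on an array ranged from 114.3 to 221.9, and correlations between arrays of a group, taken over probe sets, ranged from 0.767 to 0.971. The 3'/5' ratio of the GAPDH control, which can rise as RNA degrades, passed 3 on 10 of 34 day arrays and on 1 of 35 night arrays (Fisher's exact test, two-sided, p = 0.0029). Equal replicate numbers recurred among the high ratios of an age, and with arrays of the same age, time and number counted once, a count chosen after the values were seen, it was 7 of 19 by day and 1 of 19 by night (Fisher's exact test, p = 0.0422).

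The comparison of pineal with brain addresses which genes set the gland apart. The gene aanat2 encodes the enzyme that acetylates serotonin on the way to melatonin, and its promoter marked the dissected tissue. It was higher in pineal by a log2 change of 3.66 ± 0.15 (limma, 38 against 31 arrays, adjusted p = 1.32e-30). The largest rises were in rbp4l of the retinol-binding protein family, at 5.99 ± 0.17 or 63.4-fold, and in the transducin gamma subunits gngt1 at 5.70 ± 0.17 and gngt2a at 5.27 ± 0.18. The homeobox gene noto, needed for pineal development, was higher by 5.21 ± 0.20. Also higher were unc119.2 (4.98 ± 0.15), the vesicle protein gene syt5a (4.95 ± 0.15), the phosphodiesterase subunit pde6a (4.76 ± 0.14), the retinoid isomerase rpe65a (4.66 ± 0.14), rod transducin gnat1 (4.48 ± 0.18) and the guanylate cyclase gucy2f (4.41 ± 0.15). A second probe set of gucy2f gave 0.69. The largest falls were in the myelin gene mbpa at -4.36 ± 0.19, or 20.6-fold lower, and in cd59a at -3.82 ± 0.20. Next came the tubulin gene tubb2 (-3.11), the neuropeptide genes pmchl (-3.05) and npffl (-2.91), the transcription factor genes meis2b (-2.89) and en2a (-2.85), skeletal actin acta1a (-2.76), mab21l2 (-2.67) and the parvalbumin pvalb7 (-2.66). Sizes near background depend on the added constant: pmchl, at a mean of 4.95 in pineal, was at -4.13 with a constant of 1 and -2.02 with 64, npffl at -3.39 and -2.33, and acta1a at -3.35 and -2.09. The same limit holds for rises from near background in brain, such as noto (mean 5.59 in brain), unc119.2 (5.84) and pde6a (5.94). The 20 genes of largest rise and fall were named because they had the largest changes among those with the same sign at all 5 ages. In all, limma called 897 of 15502 probe sets, 389 higher and 508 lower in pineal.

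Among the function lists, 17 of 28 phototransduction genes rose and 0 fell, including the recoverin gene rcvrn3 (4.40 ± 0.14) and the pineal opsin exorh (4.12 ± 0.16). Adjusted over the list alone, and without the 2-fold limit that held for all genes, 22 rose and 1 fell; the other list-alone counts of this comparison and of the stage comparisons also drop that limit. Of 10 melatonin synthesis genes, tph2 (3.74 ± 0.11), ddc (2.92 ± 0.11), tph1a (3.43 ± 0.14) and aanat2 rose (6 higher and 2 lower adjusted over the list alone). Of 18 genes for photoreceptor structure and retinoid handling, 6 rose, among them stra6 (2.94) and rlbp1a (3.38), and the creatine kinase gene ckmt1 fell (8 and 2 adjusted over the list alone). Of 28 transcription factors of photoreceptors and pineal, 7 rose and 1 fell, with nr2e3 at 3.48 ± 0.11 and crx at 3.17 ± 0.13 (12 and 7 adjusted over the list alone). Of 48 genes of oxidative phosphorylation and glycolysis, 8 fell and 1 rose: ndufa4b fell by 1.41 and aldoca by 2.06, while cox4i2, an isoform of a cytochrome oxidase subunit, was higher by 1.70 (1 and 43 adjusted over the list alone; 1 and 41 by adjusted p over all genes without the 2-fold limit). All 5 lists were called by camera at the preset correlation and with an estimated one. The cell cycle list was also called upward, with 1 of 48 genes past the threshold, hmgb2a at 1.09 (15 and 0 adjusted over the list alone), and this call was lost with adjusted p = 0.107 with an estimated correlation. The lists for circadian clock (csnk1e at -1.15 the 1 call among 32 genes; 8 and 3 adjusted over the list alone), light response and DNA repair (3 of 37 rose, among them sik1 at 1.35 and dusp1 at 1.26; 12 and 5) and heme synthesis and oxidative stress (0 of 22 called; the list-alone counts were 5 and 3) were not called.

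Marker genes of other tissues also differed between pineal and brain samples. Of 32 muscle genes, 25 were lower and 1 was higher in pineal, with the calcium pump gene atp2a1 at -3.20 ± 0.22 and neb at -2.06 ± 0.14 (1 and 30 adjusted over the list alone). Of 48 neuron genes, 20 were lower and 2 higher; gad2, which makes GABA, was at -2.29 ± 0.14 and the neurofilament gene inaa at 2.87 ± 0.10 (4 and 37 adjusted over the list alone). Lower as well were 4 of 12 myelin genes (1 and 5 adjusted over the list alone) and 9 of 19 pituitary and hypothalamic hormone genes, among them uts1 at -2.07 and oxt at -2.14 (0 and 11). Skin and keratin genes were higher in 17 of 37 cases and lower in 2, with icn2 at 2.29 ± 0.13 and krt91 at 2.09 ± 0.14 (26 and 4). These 5 lists were called by camera and kept their calls with an estimated correlation, skin at adjusted p = 0.0461. For connective tissue, cartilage and bone, 9 of 37 genes were lower and 1 higher, with the cartilage gene matn1 at -2.81 ± 0.17 (6 and 20), and the list's call was lost with adjusted p = 0.148 with an estimated correlation. The immune list, with 4 of 32 genes higher (15 and 3), lost its upward call with adjusted p = 0.0897 with an estimated correlation. Its gene ctss2.2, at 1.02, fell below 2-fold when any 1 of 7 arrays was left out; psmb8a was at 1.08. The erythrocyte list, with 0 of 16 genes past the threshold (5 and 1), lost its upward call with adjusted p = 0.304 with an estimated correlation. Not called were astroglia and radial glia (id1 at 1.06, cyp19a1b at -1.22 and slc1a3a, whose call was lost when any 1 of 3 arrays was left out, among 22, with 10 and 5 adjusted over the list alone), endothelium (tpm1 at -1.92 the 1 call among 14), habenula (adcyap1a at -1.23 the 1 call among 9), pigment cells (0 of 13) and retinal opsins with lens crystallins. In the last list the median was -0.08 and the mean 0.08, with the red cone opsin opn1lw1 at 2.61 ± 0.19 the 1 call among 11.

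At single ages the marker lists differed between larval and adult fish. The median pineal-brain difference of the muscle list was -4.03 at 3 days, -4.15 at 5 days and -2.23 at 10 days, and 0.42 at 3 months and 0.27 at 1 to 2 years. The skin list had medians of -0.10, 0.04 and 0.08 at the larval ages and 2.74 and 2.97 at the adult ages, where 33 and 34 of its 37 genes rose. The neuron list went from -0.26, 0.18 and -0.26 to -1.89 and -2.17, with 39 and 41 of 48 genes lower in adult pineal. The phototransduction list had medians of 1.17, 0.95 and 1.22 in larvae and of 3.03 and 4.31 in adults. At 3 months, brain day replicate 3 had gnat1 at 9.94 and gngt2a at 9.62. The other day arrays of that group had 7.96 and 6.56 or less. This replicate may lower the difference at 3 months. limma called 740 probe sets at 3 days, 803 at 5 days, 564 at 10 days, 3294 at 3 months and 3291 at 1 to 2 years. Higher in pineal at all 5 ages were 73 probe sets, and lower at all 5 were 42. Without scaling between arrays the split into higher and lower went from 256 and 308 to 187 and 417 at 10 days, from 1691 and 1603 to 2656 and 1170 at 3 months, and from 1694 and 1597 to 2705 and 1173 at 1 to 2 years. Median centring turned the adult splits the other way, to 1515 and 2052 at 3 months and to 1515 and 2007 at 1 to 2 years. Before normalization, the median intensity averaged 183.1 on adult pineal arrays and 139.5 on adult brain arrays. On larval pineal and brain arrays it averaged 142.8 and 151.8. The choice of scaling is therefore bound up with adult pineal, and the adult splits cannot tell a real difference in signal from a technical one.

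**Figure D1:**
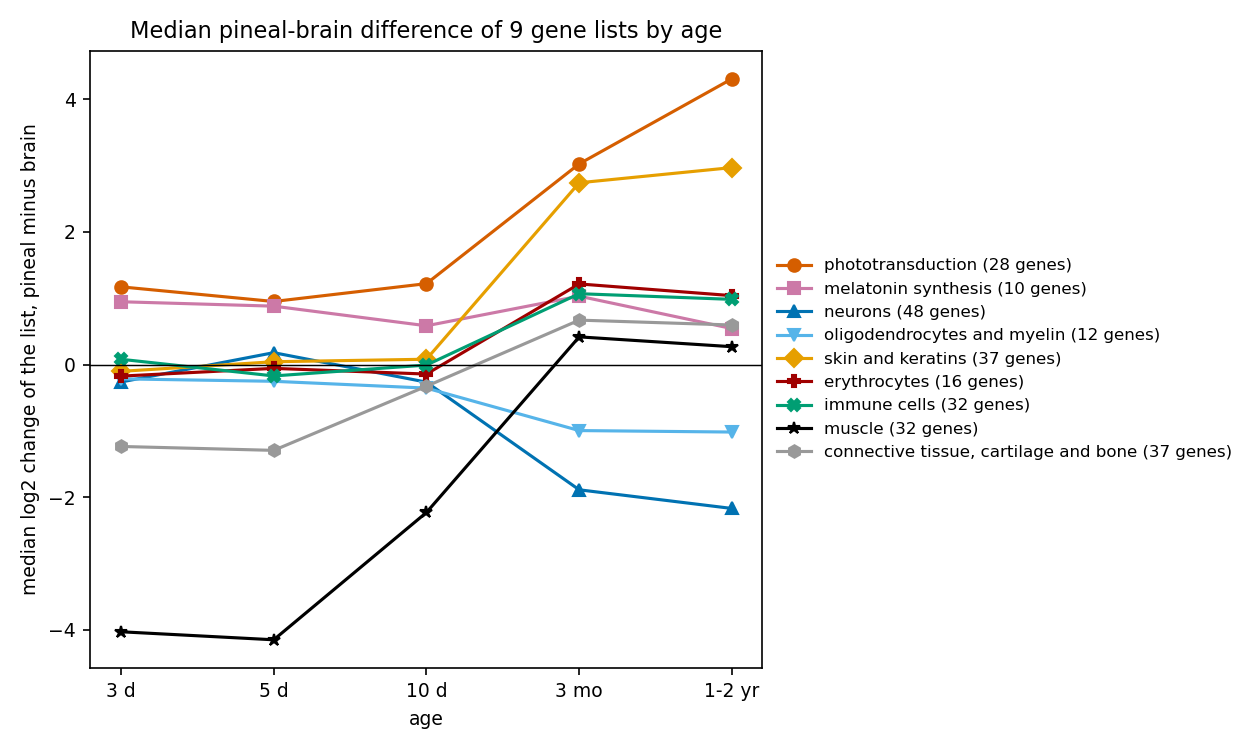
Median log2 difference between pineal and brain (vertical axis) at each age (horizontal axis) for 9 gene lists, 1 line per list, with the number of measured genes in the legend. The muscle list lies at -4.03 at 3 days and at 0.27 at 1 to 2 years, the skin list at -0.10 and at 2.97, and the phototransduction list above 0 at each of the 5 ages.

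The comparison of night with day in pineal addresses which genes of the gland follow the daily cycle. At night aanat2 rose by 2.39 ± 0.21 (limma, 19 night against 19 day arrays, adjusted p = 6.81e-14) and bhlhe41, a transcriptional repressor of the clock, by 2.16 ± 0.15. Also higher at night were the steroid hydroxylase gene cyp11c1 (1.79 ± 0.26), tph1a of serotonin synthesis (1.37 ± 0.18), guca1aa, an activator of guanylate cyclase (1.31 ± 0.22), pja2 (1.28), the F-box gene fbxo25 (1.25), the clock repressor ciarta (1.14), dtx4a (2.14-fold) and the transcription factor gene mef2ca (1.02). Lower at night were rbp3, which carries retinoids between photoreceptors and their neighbours (-2.64 ± 0.25), the light-induced clock gene per2 (-2.59 ± 0.27), the cone phosphodiesterase subunit pde6ha (-2.44 ± 0.24), prxl2b (-1.72), nfil3-6 (-1.68), rbp4l (-1.59), rbp4 (-1.54), the chaperone gene hsp90aa1.2 (-1.48), nfil3-5 (-1.28) and cyp27c1, which converts vitamin A1 to A2 (-1.25). A shared sign at all 5 ages was a condition for naming these 20 genes. The size for cyp11c1, at a mean of 5.85 by day, depends on the added constant, with 2.39 for a constant of 1 and 1.16 for 64. limma called 409 probe sets, 208 higher and 201 lower at night, and 59 of these changed at least 2-fold. With only the 38 pineal arrays in the fit the count was 235, with 115 higher and 120 lower.

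Of 10 melatonin synthesis genes, aanat2, tph1a and qdpra (0.83) rose and mao fell by 0.56 (4 and 1 adjusted over the list alone). This list was called upward with both correlations, adjusted p = 0.0155 with an estimated correlation. Among 32 clock genes, 3 rose and 8 fell (5 and 9 adjusted over the list alone), with bhlhe41, ciarta, per2, nfil3-5, nfil3-6, rorab (-0.78) and bmal1a (-1.17) among them, and the list's downward call was lost with adjusted p = 0.275 with an estimated correlation. Of 37 light-responsive and DNA repair genes, 9 fell and 1 rose (3 and 9 adjusted over the list alone), including neil1 of base excision repair (-1.17), the photolyase gene cpdp (-0.78) and sik1 (0.66). Its downward call had adjusted p = 0.129 with an estimated correlation. Of 48 genes of oxidative phosphorylation and glycolysis, 9 fell and 1 rose (2 and 12), with the succinate dehydrogenase genes sdha and sdhb at -0.70 and -0.81; here adjusted p = 0.275 with an estimated correlation. Phototransduction was called downward, with 4 of 28 genes lower and 1 higher (1 and 6), among them pde6ha, rcvrn3 (-1.14) and guca1aa; adjusted p = 0.297 with an estimated correlation. In photoreceptor structure and retinoid handling, rbp3 and rbp4l fell (0 and 4), and the downward call had adjusted p = 0.194 with an estimated correlation. The neuron list was called upward with 3 of 48 genes higher (5 and 0), among them snap25b at 0.42, and lost the call with adjusted p = 0.297 with an estimated correlation. Skin (1 of 37 lower, 0 and 1) and cell cycle (0 of 48, 0 and 0) were called downward, with adjusted p = 0.513 and adjusted p = 0.275 with an estimated correlation. The other 13 lists were not called; in connective tissue the median was 0.02, the mean -0.05 and the test downward.

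**Figure D2:**
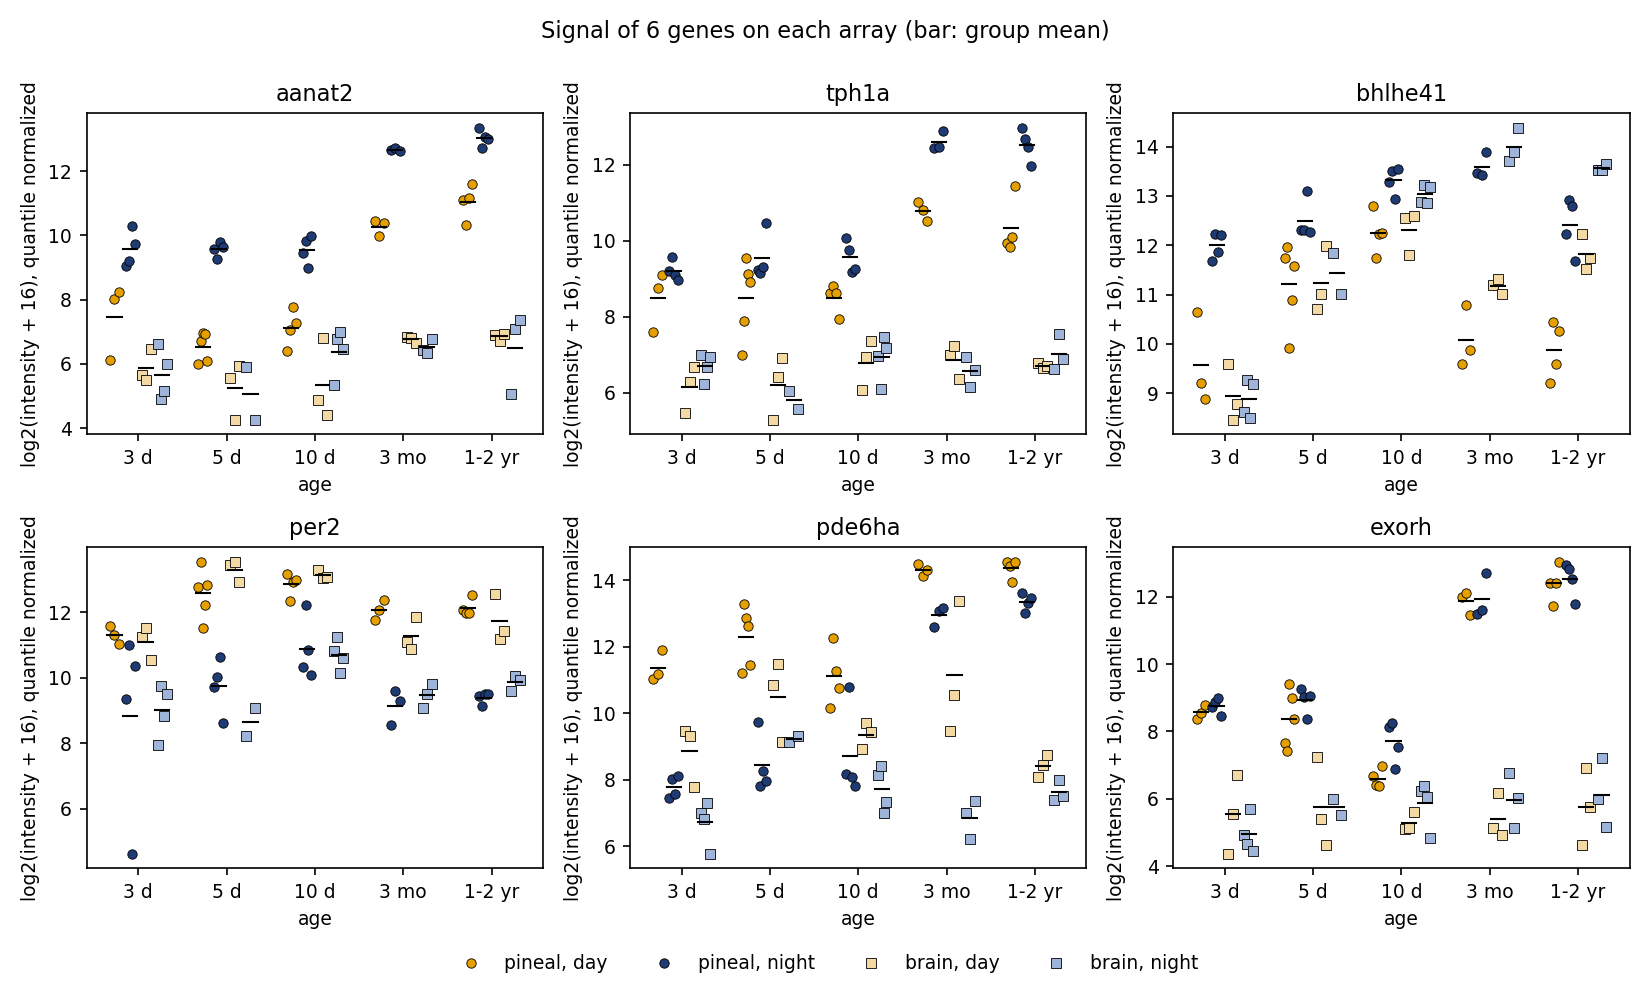
Quantile-normalized log2 signal (vertical axis) of aanat2, tph1a, bhlhe41, per2, pde6ha and exorh on each array by age (horizontal axis), with circles for pineal, squares for brain, colours for day and night, and a bar at each group mean. In pineal, aanat2 averaged 6.54 by day and 9.57 by night at 5 days, and 11.05 and 13.04 at 1 to 2 years.

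Some night-day differences in pineal varied with age. For nfil3-5 the change was -0.02 ± 0.31 at 3 days, -0.46 ± 0.28 at 5 days, -0.75 ± 0.29 at 10 days, -2.32 ± 0.34 at 3 months and -2.87 ± 0.29 at 1 to 2 years (limma F-test across ages, adjusted p = 1.30e-05). For ciarta it was 0.21, 0.51 and 0.34 at the larval ages, then 3.03 at 3 months and 1.61 at 1 to 2 years (adjusted p = 0.00198). For bhlhe41 it ranged from 1.07 at 10 days to 3.51 at 3 months (adjusted p = 0.0175), and for cyp27c1 from -0.41 at 3 days to -3.06 at 1 to 2 years (adjusted p = 0.0094). The night rise of aanat2 was 2.11 ± 0.48, 3.04 ± 0.42, 2.43 ± 0.44, 2.39 ± 0.51 and 1.99 ± 0.44 from the youngest to the oldest fish. The F-test called 40 probe sets, and 7 with only the pineal arrays in the fit; the count was 26 without 3mo pineal night replicate 3, 81 without 5d pineal day replicate 2, 95 without 10d pineal day replicate 1 and 67 without 10d pineal day replicate 4. At single ages limma called 201, 65, 91, 39 and 65 probe sets, and these counts depended on single arrays: they ranged over 69 to 296, 35 to 115, 24 to 239, 15 to 42 and 28 to 110 when 1 array was left out. With median centring the 3-month split of 24 higher and 15 lower became 10 and 10.

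Night and day were also compared in brain. At night per2 fell by 2.57 ± 0.29 (limma, 16 night against 15 day arrays, adjusted p = 5.92e-09), nfil3-6 by 1.54 ± 0.25 and nfil3-5 by 1.16 ± 0.15, while ciarta rose by 1.40 ± 0.17 and bhlhe41 by 1.08 ± 0.17. The photolyase-family gene cry5 fell by 1.63, neil1 by 1.46, cry-dash by 0.98, cpdp by 0.90 and the DNA damage gene ddb2 by 0.87. Also lower were pde6ha (-2.02 ± 0.27), rbp4 (-1.56 ± 0.16) and sdha (-0.76). On 3mo brain day replicate 3, pde6ha was at 13.38 and rbp3 at 9.14, against 10.56 and 6.90 or less on the other arrays of that group. The calls of rbp3 (-1.12) and rbp4l (adjusted p = 0.0335) were lost when any 1 of 8 and of 16 arrays was left out. limma called 143 probe sets, 58 higher and 85 lower, and 82 to 366 when 1 array was left out. The split turned to 841 higher and 610 lower with array weights and to 146 and 96 without the 5-day fish. It turned as well with a replicate block and without the 10-day fish. By age, limma called 13 probe sets at 3 days, 29 at 5 days, 11 at 10 days, 25 at 3 months and 137 at 1 to 2 years, the age at which GAPDH ratios of brain day arrays reached 13.8 and 17.2. With the log2 GAPDH ratio in the fit the count was 51, and without the 11 arrays above a ratio of 3 it was 38, with 43 and 37 of the 143 calls among them; in pineal the counts were 431 and 400, with 396 and 298 of the 409 calls among them. Of 32 clock genes, 2 rose and 6 fell (3 and 10 adjusted over the list alone; adjusted p = 0.329 with an estimated correlation), and of 37 light-responsive and DNA repair genes 7 fell (1 and 8; adjusted p = 0.329 with an estimated correlation). The lists for phototransduction (1 of 28 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.355 with an estimated correlation) and for oxidative phosphorylation and glycolysis (4 of 48 lower, 0 and 6, adjusted p = 0.632 with an estimated correlation) were called downward as well. So was muscle (0 of 32), and neurons (0 of 48) were called upward, each with adjusted p = 0.632 with an estimated correlation. None of the 10 melatonin synthesis genes was called. For the transcription factor list the median was -0.02 and the mean -0.01 while its test, at adjusted p = 0.881, pointed upward.

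Pineal and brain shared 22 probe sets higher at night, where 0.778 would be expected if the calls were independent (exact hypergeometric test, p = 7.66e-27), and 47 lower, where 1.1 would be expected (p = 8.89e-68). These p-values treat probe sets and tissues as independent. Yet 20 of 31 pineal-brain pairs matched best with their own number, against 10 expected. GAPDH ratios above 3 fell on 4 pineal and 6 brain day arrays. Shared handling or RNA quality was therefore not separated from a shared daily change. In the test of whether the night-day change differed between the tissues, aanat2 differed most clearly, with a change of 2.39 in pineal and 0.01 in brain (limma, difference 2.38 ± 0.31, adjusted p = 8.08e-07). The night-day change was also higher in pineal for cyp11c1 (1.79 in pineal against -0.57 in brain, difference 2.36 ± 0.39, adjusted p = 0.000322, and 3.30 and 1.44 with constants of 1 and 64). So it was for rgcc, a regulator of the cell cycle (1.01 in pineal against -0.20 in brain, difference 1.21 ± 0.23). The night rise was larger in pineal for tph1a (1.37 in pineal against 0.07 in brain, adjusted p = 0.018) and bhlhe41 (difference 1.08 ± 0.23, adjusted p = 0.0213). For the centrin gene cetn4 the difference was -1.30 ± 0.23, with -0.97 in pineal and 0.33 in brain. Over all settings the call of aanat2 was lost in 0, those of cyp11c1 and cetn4 in 1, without the fish of 1 to 2 years, and those of rgcc, tph1a and bhlhe41 in 3, 5 and 8, at adjusted p up to 0.423, 0.477 and 0.689. The call of tph1a was lost when 1 of the 69 arrays was left out, that of bhlhe41 with 3, and those of grtp1a, sik1, akap9, magi1b and nptna with 46, 34, 55, 39 and 50. limma called 20 probe sets, 16 with a higher change in pineal and 4 with a lower one, and 885 had an unadjusted p below 0.05. The count ranged from 9 to 28 when 1 array was left out, and 33 omissions moved it beyond 1.5 times. With median centring the split was 6 and 4, and with array weights 54 and 33.

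**Figure D3:**
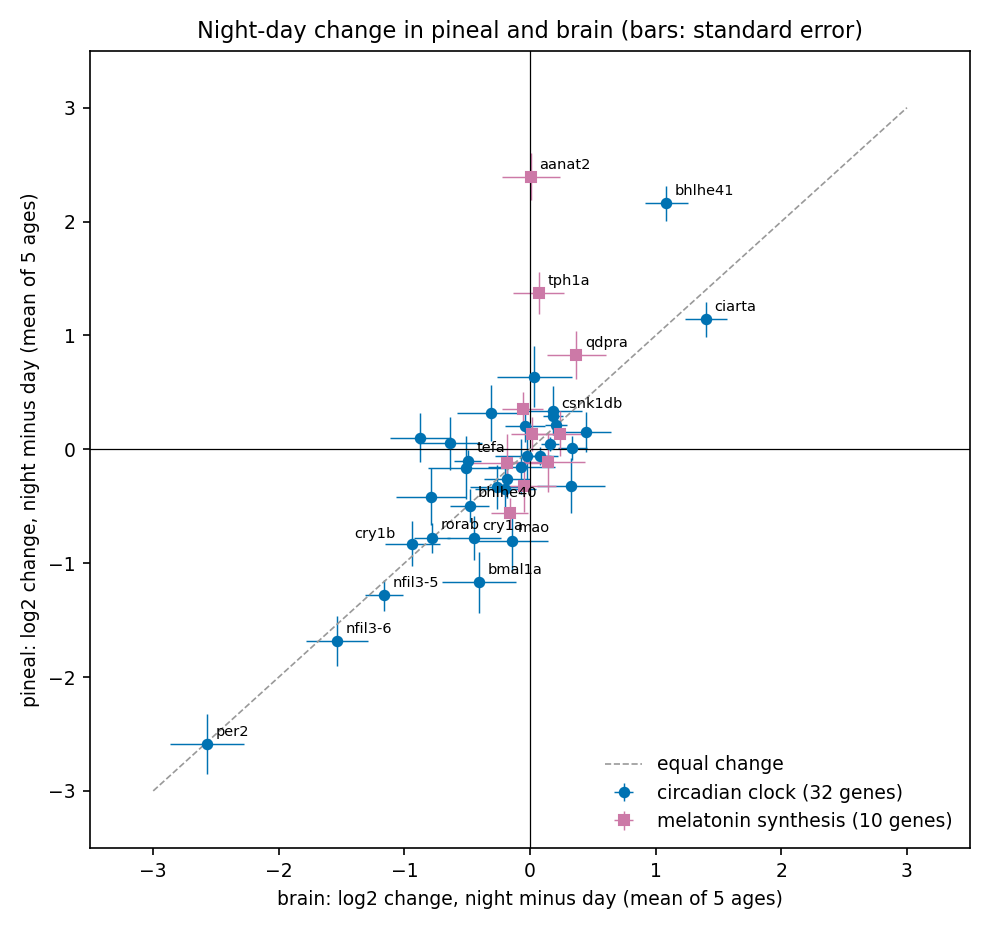
Log2 change from day to night in brain (horizontal axis) and in pineal (vertical axis) for the 32 clock genes and 10 melatonin synthesis genes, 1 point per gene with standard error bars, and a dashed line of equal change. The point for per2 lies at -2.57 and -2.59 and the point for aanat2 at 0.01 and 2.39.

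**Figure D4:**
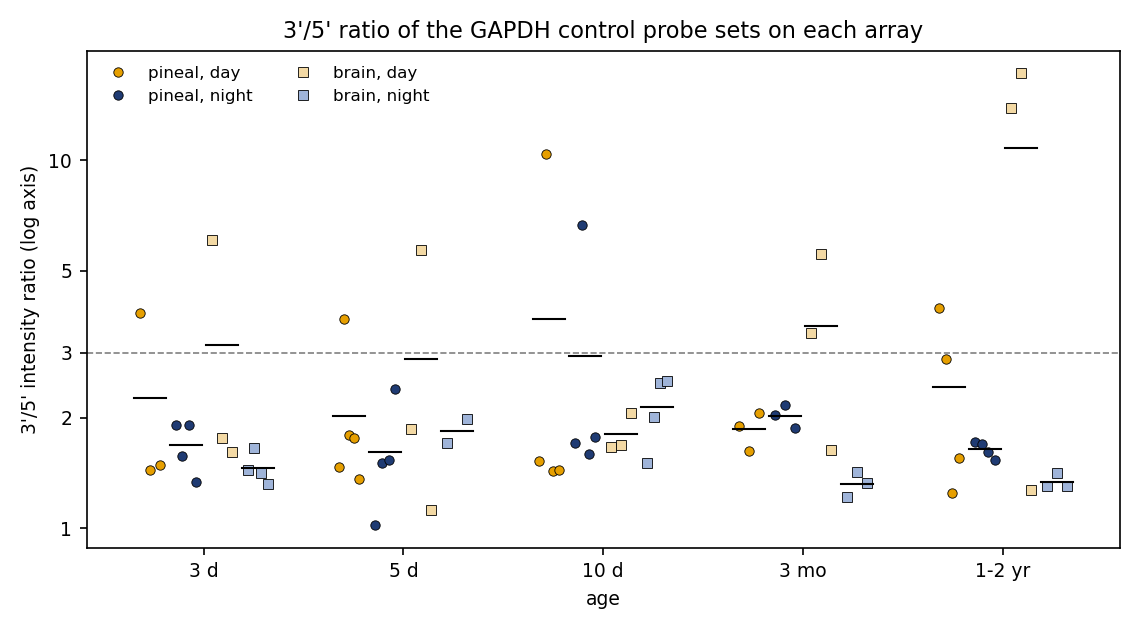
Ratio of 3' to 5' GAPDH signal on each array (vertical axis, log scale) by group (horizontal axis), with a bar at each group mean and a dashed line at 3. The highest ratio, 17.2, was on a brain day array, and 10 of the 11 arrays above the line were taken by day.

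Adult pineal differed from larval pineal in pineal genes and in markers of blood and immune cells. The globin gene hbaa1 rose by 8.82 ± 0.29 (limma, 14 adult against 24 larval arrays, adjusted p = 3.84e-36), and the invariant chain genes of antigen presentation cd74a and cd74b rose by 7.09 ± 0.22 and 5.30 ± 0.24. Next came the red cone opsin opn1lw1 (6.05 ± 0.27), hbba2 (5.69), b2m of class I antigen presentation (5.53), tcimb (5.31), ogfr2 (5.24), the complement gene cfd (5.20) and the interferon-inducible ifi27.1 (5.17). Sizes for genes near background in larvae depend on the added constant: hbaa1, at a mean of 5.62 in larval pineal, rose by 9.71 with a constant of 1 and by 7.73 with 64, cd74a by 7.91 and 5.97, and hbba2 by 6.53 and 4.62. The erythrocyte genes slc4a1a and cahz, higher than hbaa1 in larval pineal, rose less, from 7.75 to 11.89 and from 7.55 to 11.32. The size for hbaa1 alone is therefore no measure of blood content. Lower in adult pineal were krt1-19e (-4.68 ± 0.23), lmo3 (-3.99 ± 0.16), the growth-linked RNA-binding gene igf2bp1 (-3.41), irx1b (-3.41), barhl2 (-3.34), nr2f1b (-3.23), zic2b (-3.22), foxb1a (-3.14), nr2f2 (-3.13) and gad2 (-3.13). The same limit held for falls to near background in adults: igf2bp1, at a mean of 5.44 in adult pineal, was at -4.17 with a constant of 1 and -2.46 with 64, irx1b at -3.96 and -2.61, and nr2f1b at -4.14 and -2.20. In melatonin synthesis, tph2 (3.25), aanat2 (3.45 ± 0.21), ddc (2.30) and a 4th gene of 10 rose, and gch2 fell by 2.12 (7 and 1 adjusted over the list alone). In phototransduction 18 of 28 rose and 1 fell (20 and 1), with guca1aa at 4.86, exorh at 4.02 ± 0.23 and rgs9b at -2.45. Erythrocyte genes rose in 13 of 16 cases and fell in 2 (13 and 2), immune genes in 20 of 32 (23 and 4), genes of heme synthesis and oxidative stress in 10 of 22, gpx1a at 3.48 among them (17 and 1), and endothelial genes in 3 of 14, kdrl at 1.94 among them (9 and 1). These 6 lists were called upward with both correlations. limma called 2417 probe sets, 1311 higher and 1106 lower in adults. Without scaling the median of all genes moved by 0.28, and the split was 2243 and 751, while with median centring it was 1139 and 1381.

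The other calls in this comparison rested on the preset correlation. The neuron list was called downward, with 24 of 48 lower and 5 higher, such as neurod6b at -3.08 and inaa at 2.38 (6 and 34 adjusted over the list alone; adjusted p = 0.0505 with an estimated correlation). Cell cycle genes were lower in 10 of 48 cases, with the cyclin gene ccnd1 at -1.81 and mcm7 at -1.63 (1 and 26; adjusted p = 0.0505 with an estimated correlation). Among transcription factors of photoreceptors and pineal, 7 of 28 were lower and 3 higher, with insm1b at -2.95 and tbx2b at 2.03 (7 and 14; adjusted p = 0.0505 with an estimated correlation). Photoreceptor structure had 7 of 18 higher and 1 lower, with unc119.2 at 3.54 (10 and 1; adjusted p = 0.0505 with an estimated correlation). Skin had 14 of 37 higher and 4 lower, with krt94 at 3.85 (18 and 5; adjusted p = 0.4 with an estimated correlation), and oxidative phosphorylation had 3 of 48 higher, with cox4i2 4.28-fold higher (27 and 3; adjusted p = 0.318 with an estimated correlation). The other 10 lists were not called. The clock list, with ciarta at -1.83 and nfil3-6 at 1.66, had 6 and 11 of 32 genes called over the list alone. In the myelin list the median was -0.29, the mean 0.24 and the test downward, with mbpa at 4.36 and cd59a at 3.51.

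Adult and larval brain also differed, in gene groups that were counted here and not tested as sets. Muscle genes fell in 28 of 32 cases in adult brain (1 and 31 adjusted over the list alone), with mylpfa at -6.78 ± 0.42 and the parvalbumin pvalb1 at -6.76 ± 0.40 (limma, 12 adult against 19 larval arrays). Skin genes fell in 31 of 37 cases (0 and 32), krt4 by 4.49, and connective tissue genes in 20 of 37 (1 and 29), with the cartilage collagen col2a1a at -6.06 ± 0.25. Neuron genes rose in 18 of 48 cases (31 and 1 adjusted over the list alone), with snap25b at 1.34 ± 0.09 and nrgna at 2.57, and so did the radial glial aromatase cyp19a1b (6.72 ± 0.29), s100b (3.54), hbaa1 (8.73) and the peptide hormone gene oxt (4.54). Cell cycle genes fell in 10 of 48 cases (0 and 25), with ccnd1 at -1.76, and 10 had fallen in pineal. Like hbaa1, the genes cyp19a1b and s100b had risen in adult pineal too, by 3.79 and 2.79. limma called 1797 probe sets, 773 higher and 1024 lower.

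The test of whether the stage change differed between pineal and brain called 30 muscle genes of 32 upward and 1 downward, with actc1b at 5.96 ± 0.41, from 0.94 in pineal and -5.02 in brain (31 and 1 adjusted over the list alone). Skin had 32 of 37 upward, with krt1-19d at 7.95 ± 0.41 (35 and 0), connective tissue 26 of 37 (31 and 0), erythrocytes 14 of 16 (14 and 0) and immune cells 19 of 32, b2m at 2.77 among them (21 and 3). Neurons had 36 of 48 downward and 2 upward, with gad2 at -4.01 ± 0.29, from -3.13 in pineal and 0.89 in brain (2 and 43). Phototransduction had 20 of 28 upward and 1 downward, with guca1aa at 5.13 ± 0.33 and exorh at 3.72 ± 0.34 (21 and 1), and melatonin synthesis 4 of 10 upward and 1 downward, with tph2 at 3.19 (4 and 1). Also called were endothelium (4 of 14 upward; 7 and 1), heme synthesis (5 of 22 upward; 11 and 0), habenula (5 of 9 downward and 1 upward, kctd12.1 at -3.20; 2 and 5) and astroglia (7 of 22 downward and 1 upward, mdkb at -2.31; 5 and 12). These 12 lists kept their calls with an estimated correlation. Retinal opsins (5 of 11 upward, 6 and 0) lost theirs with adjusted p = 0.0859 with an estimated correlation, and oxidative phosphorylation, called downward by its test (3 of 48 downward, ndufa4b at -1.75 among them, and 5 upward, gapdh at 5.20 among them; 5 and 21), with adjusted p = 0.441 with an estimated correlation. The median, mean and test differed in sign for photoreceptor structure (-0.01, 0.55, upward), pigment cells (-0.07, 0.18, upward) and hormones (0.07, -0.52, downward), none of them called. limma called 3530 probe sets, 1910 upward and 1620 downward. Without scaling the median of all genes moved by 0.30 and the split was 3277 and 977; with median centring that median was -0.13 and the split 1834 and 1994.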

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

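The tests of RNA quality on the pineal calls and on the size of the brain change, and the tests of a lower share of neurons or of pineal cells, were chosen only after the results were seen; the other tests were chosen before they were run.

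RNA quality is a hypothesis for the night-day calls, since mean log2 GAPDH ratios were 1.56 by day and 0.663 by night in brain and 1.04 and 0.859 in pineal. In pineal it may add little: a share of 0.968 of the calls remained with the ratio in the fit, which goes against it as the main cause, though without the 11 arrays above a ratio of 3 only 298 of the 409 calls were among the 400 made. In brain RNA quality may contribute: within pineal groups the slopes on the ratio had the sign of the brain change for a share of 0.762 of the called probe sets (permutation p = 0.018, permuted median 0.476). For per2, at -2.54 with the GAPDH ratio in the fit, the values argue against RNA quality as the whole of the brain change. For the calls as a set this stays undecided. With the ratio in the fit all 143 kept their sign at a median ratio of 0.751 to their size without it (0.680 without the 11 arrays, where 37 stayed called). Adjusting for 1 control ratio may remove only part of an effect of RNA quality. With the ratio in the fit 43 stayed called, because the median size went from 0.783 to 0.554 while the median standard error went from 0.158 to 0.162, so how much of the other changes is a daily rhythm stays open. RNA quality was judged by the GAPDH control alone. The acta1 control gave a mixed picture and cannot decide. Its ratio ranged from 0.328 to 747 over the arrays, and the gene acta1a averaged 5.66 in pineal, near background. On 1yr brain day replicates 1 and 2, with GAPDH ratios of 13.8 and 17.2, the acta1 ratio was 1.01 and 1.36. It was 67.4 on replicate 3, with a GAPDH ratio of 1.27. On 3d brain day replicate 1, with a GAPDH ratio of 6.09, it was 142, against 15.8 and 17.1 on replicates 2 and 3.

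Head muscle and cartilage carried over in the larval brain samples is a hypothesis for the low muscle values of larval pineal relative to brain, and may fit the mean residual correlation of 0.514 among muscle genes across larval brain arrays (0 of 1000 random lists as high), against 0.180 in larval pineal and 0.184 in adult pineal, each also with 0 of 1000, and 0.0705 in adult brain with 6 of 1000. Scaling is unlikely, as the median at 3 days was -4.09 without it, and so is a lower share of neurons, as the medians of 3 other lists lay at least 3.85 above that of muscle. Of these lists, mainly skin carries weight, with 32 of 37 genes above the median gene in larval brain and 28 in larval pineal. For erythrocytes these counts were 7 and 6 of 16, and for immune cells 9 and 7 of 32, so most of their genes were too low to shift. The gene pvalb1 had a level of 13.91 in larval brain and 7.15 in adult brain, and mylpfa 13.07 and 6.28. Of the 32 muscle genes, 28 lay above the median gene in larval brain and 2 in adult brain, 4 in larval pineal and 7 in adult pineal, and 1 was in another list. A real difference between larval and adult brain stays open and was not tested.

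Skin and skull tissue carried over in the adult pineal samples is a hypothesis for the high skin, blood and immune values there, and may fit the mean residual correlation of 0.503 among skin genes across adult pineal arrays (0 of 1000 random lists as high). The correlation was not particular to these samples: it was 0.329 in larval brain, 0.200 in adult brain and 0.164 in larval pineal, each with 0 of 1000 random lists as high. Scaling is unlikely, as the skin median without it stayed at 2.62 above that of all genes. From larval to adult pineal, the smaller of the distances of the erythrocyte median above those of neurons and myelin was 3.30. Other lists argue against a lower share of pineal cells that raises all other cell types. From larval to adult pineal 18 of 28 phototransduction genes rose and 1 fell, while 24 of 48 neuron genes were lower and 5 higher. The neuron list lost its call with an estimated correlation, and changes of level within a cell type were not tested. The erythrocyte distance itself cannot decide on that share, because blood genes rose with age in brain too. There cahz went from 7.93 to 10.37, slc4a1a from 8.70 to 10.03 and aqp1a.1 from 9.44 to 9.64. The rise of hbaa1 in brain, from 5.47 to 14.20, started near background and need not follow the amount of blood. In larval pineal, adult pineal, larval brain and adult brain, icn2 had levels of 14.23, 14.75, 13.43 and 10.24 and krt5 of 13.15, 12.97, 12.02 and 8.67, so for these genes the adult difference went with lower values in adult brain, while from larval to adult pineal icn went from 12.18 to 14.21, krt97 from 11.94 to 12.65 and cd74a from 5.46 to 12.55 (11.54 in adult brain). Of the 37 skin genes, 31 lay above the median gene in adult pineal, 28 in larval pineal and 11 in adult brain, with 0 in another list, as did 13 of 16 erythrocyte and 21 of 32 immune genes in adult pineal; skin carried over at both stages, and blood and immune cells within the adult gland, stay open and were not tested.

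Relabelling the arrays within the other factors gave the following highest counts in any other split, with the real count reached by 1 of 100 splits unless stated. For comparisons between tissues, sampling times or stages, chance can so be excluded at a share under 0.05, with the exceptions below. This holds only if the arrays are independent, which equal numbers handled together would break. The splits also cannot exclude handling or RNA quality that differed between the groups compared. For tissue by time, tissue by stage and the F-test, relabelling also removed the tissue or night-day effect itself. Their splits therefore cannot exclude chance for a difference between changes. The highest other count was 52 for pineal against brain (897), 362 at 3 days (740), 369 at 5 days (803), 255 at 10 days (564), 2066 at 3 months (3294) and 954 at 1 to 2 years (3291). It was 11 for night against day in pineal (409), 2 in brain (143), 2 for tissue by time (20), 314 and 230 for adult against larval pineal (2417) and brain (1797), and 842 for tissue by stage (3530). It was 15 at 3 days (201; 1 of 35 splits), 56 at 10 days (91; 1 of 35) and 42 for the F-test over ages (40; 2 of 100). Chance cannot be excluded for night against day in pineal at 5 days, where 11 of 100 splits reached 65 and the highest other was 357, or at 1 to 2 years, where 4 of 35 reached 65 and the highest other was 175. At 5 days 2 splits called several times the real count, which points to structure among those samples. At 3 months the 10 splits are too few for a share under 0.05; the real count was 39, reached by 1, and the highest other 6.

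Single arrays lay apart from their group in 14 of 117 groups of values, where 5.85 would be expected at 1 in 20. For tph1a, 5d pineal night replicate 4 was at 10.45 and the others at 9.16 to 9.32, and 1yr pineal day replicate 4 at 11.44 and the others at 9.83 to 10.10. For bhlhe41, 5d pineal night replicate 3 was at 13.10 and the others at 12.27 to 12.31. For pde6ha, 10d pineal night replicate 2 was at 10.78 and the others at 7.81 to 8.16, and for gngt1, 5d pineal day replicate 2 was at 10.74 and the others at 12.63 to 13.37. For rbp4l, 10d brain night replicate 2 was at 7.95 and the others at 6.73 to 6.84. For krt1-19d, 3d pineal night replicate 2 was at 5.77 and the others at 4.88 to 4.91, and 1yr pineal day replicate 3 at 7.47 and the others at 9.40 to 9.60. For hbaa1, 5d pineal night replicate 1 was at 7.79 (others 5.51 to 5.87), 10d brain night replicate 3 at 5.75 (4.16 to 4.30) and 1yr pineal day replicate 2 at 14.47 (14.96 to 15.03). The GAPDH ratio was 3.70 on 5d pineal day replicate 2 (others 1.36 to 1.79), 10.4 on 10d pineal day replicate 2 (1.43 to 1.53) and 6.67 on 10d pineal night replicate 2 (1.59 to 1.77). Differences between groups called 20 probe sets for tissue by time, 40 for night-day by age and 3530 probe sets and 14 lists for tissue by stage.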

How the results depend on the processing

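Most counts stayed within 1.5 times the value in the report and no named gene changed sign past its threshold, but the balance of higher and lower calls was less stable than the counts, and the cause was not tested where a count or balance moved unless named. With median centring the larger side turned for pineal against brain at 3 months (1515 higher and 2052 lower) and at 1 to 2 years (1515 and 2007), for adult against larval pineal (1139 and 1381) and for tissue by stage (1834 and 1994), and adjusted p alone turned it for these and for adult against larval brain (2954 and 2532). For night-day in brain it turned with array weights (841 and 610), with the replicate block, without 5 days (146 and 96) and without 10 days (98 and 84), and for tissue by time without 3 months (3 and 5) and without 1 to 2 years (2 and 3). The nearly even splits of night-day in pineal, over all ages and at 10 days, turned in several settings. Without scaling, night-day in pineal at 1 to 2 years moved to 33. With median centring, night-day counts moved to 20 at 3 months, 29 at 1 to 2 years, 82 in brain, 10 for tissue by time and 22 for the F-test over ages. With a constant of 64, pineal against brain at 10 days moved to 357, the F-test to 69 and adult against larval brain to 1187. Without the intensity trend, counts were 43 at 1 to 2 years, 90 in brain and 9 for tissue by time. Array weights gave 32, 16, 107 and 127 for night-day in pineal at 5 days, 10 days, 3 months and 1 to 2 years, 1451 in brain and 87 for tissue by time. With only the arrays compared, the counts were 517 for pineal against brain at 5 days, 235 for night-day in pineal, 12, 11, 59 and 26 at 5 days, 10 days, 3 months and 1 to 2 years, 7 for the F-test and 372 in brain; this setting is identical for pineal against brain, tissue by time and tissue by stage. By construction, adjusted p alone gave 5806 for pineal against brain, 4980 at 1 to 2 years, 7353 and 5486 for adult against larval pineal and brain, and 5721 for tissue by stage, and a 2-fold limit gave 59, 43 and 13 for night-day in pineal, in brain and tissue by time. Leaving out an age, which leaves fewer arrays, gave for night-day in pineal 251 without 3 days and 228 without 1 to 2 years; in brain 69, 242, 66 and 85 without 3 days, 5 days, 3 months and 1 to 2 years; for tissue by time 8 and 5 without 3 months and 1 to 2 years; and for the F-test 15, 103, 24 and 15 without 3 days, 5 days, 10 days and 3 months. Alternatives chosen after the data were seen gave 51 in brain and 92 for the F-test with the GAPDH ratio as covariate, 479, 38, 38, 9 and 112 for night-day at 3 days, at 10 days, in brain, tissue by time and the F-test without the 11 arrays above a ratio of 3, and 115 probe sets called for pineal against brain at all 5 ages. An estimated correlation left 1 of 9 lists called for night-day in pineal, 0 of 6 in brain and 6 of 12 for adult against larval pineal; fry called 1 in brain and 20 for adult against larval pineal. Leaving out 1 array in turn gave 872 to 934 for pineal against brain, 657 to 793, 552 to 912, 466 to 626, 3007 to 3428 and 3117 to 3384 from the youngest to the oldest fish, 336 to 461 for night-day in pineal, 69 to 296, 35 to 115, 24 to 239, 15 to 42 and 28 to 110 by age, 82 to 366 in brain, 9 to 28 for tissue by time (33 omissions moved it beyond 1.5 times), 26 to 95 for the F-test, 2369 to 2518 and 1748 to 1846 for adult against larval pineal and brain, and 3455 to 3628 for tissue by stage. The arrays that moved night-day in pineal were, at 3 days, pineal day replicate 3 (71) and night replicates 1 (116) and 3 (69); at 5 days, day replicates 3 (115) and 4 (113) and night replicates 2 (35) and 4 (42); at 10 days, day replicates 1 (239), 2 (24) and 4 (175) and night replicates 1 (41), 3 (45) and 4 (52); at 3 months, day replicates 1 (15) and 2 (23) and night replicate 3 (25); and at 1 to 2 years, day replicates 1 (30), 2 (36) and 4 (110) and night replicates 1 (41) and 3 (28). In brain they were 5d night replicates 1 (94) and 2 (82) and 1yr day replicates 1 (90), 2 (89) and 3 (366); the 5d omissions leave 1 array, assumed to vary like the other groups. For the F-test they were 5d pineal day replicate 2 (81), 10d pineal day replicates 1 (95) and 4 (67) and 3mo pineal night replicate 3 (26). With a replicate block the counts were 915 for pineal against brain, 795, 683, 673, 3383 and 3294 by age, 437 for night-day in pineal, 222, 44, 62, 38 and 83 by age, 198 in brain (103 higher and 95 lower), 26 for tissue by time, 37 for the F-test and 3579 for tissue by stage; the labels do not say that equal numbers share fish, and the rule for pairing was not met (11 of 31 pineal-brain pairs and 2 of 32 day-night pairs had a residual correlation over 0.1), so the block was not used in the report and not run for the stage comparisons. More samples matched best with their own number than by chance (20 against 10.0 expected, permutation p = 0.004, and 17 against 9.25, permutation p = 0.009), a hint from the data that some equal numbers were handled together, so the arrays may not be fully independent. Of 372 values for named genes, the call was lost for 17 without scaling, 32 with median centring, 32 with a constant of 64, 12 with the GAPDH ratio, 29 without the 11 arrays of high ratio, 29, 21, 24, 36 and 43 without 3 days, 5 days, 10 days, 3 months and 1 to 2 years, 29 when any 1 array was left out and 10 or fewer in each other setting, and 0 reversed.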

Other observations

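On the brain arrays taken by day at 3 months, genes of retinal photoreceptors, chosen after values were seen, differed between replicates. Replicate 3 had log2 levels of 9.69 for the red cone opsin opn1lw1, 10.89 for the green cone opsin opn1mw2, 10.54 for the blue cone opsin opn1sw2, 13.38 for pde6ha, 9.94 for gnat1 and 9.14 for rbp3, while the pineal genes exorh and aanat2 were at 4.93 and 6.66. Replicates 1 and 2 had opn1lw1 at 6.16 and 7.05, opn1mw2 at 7.33 and 7.88, and pde6ha at 9.48 and 10.56. Retinal tissue in replicate 3 is a hypothesis that was not tested, and it may raise the brain day values of these genes. Without replicate 3 the night change in brain was -1.79 for pde6ha, which stayed called, -0.95 for rbp3 (adjusted p = 0.053) and -1.13 for opn1mw2 (adjusted p = 0.0559, against -1.35 ± 0.33 with it). The call of opn1mw2 was also lost without 5d brain night replicate 2 or 10d brain day replicate 3, and in 9 settings in all.

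Night-day changes of further single genes in pineal varied with age; ndufs5 was chosen after its values were seen. The change of tspo, a mitochondrial membrane protein gene, was -0.47 at 3 days, -1.08 at 5 days, -1.82 at 10 days, 0.49 at 3 months and 0.09 at 1 to 2 years (limma F-test, adjusted p = 0.0411). For bhlhe40, a clock repressor, it was 0.23, -0.60, -0.41, 0.27 and -1.96 (adjusted p = 0.0185), and for ndufs5 of respiratory complex I it was -1.34, 0.26, 0.67, -0.14 and -0.83 (adjusted p = 0.00106).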
